A study of Mus musculus with 6 samples.

How the data were processed

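Total RNA of RAW 264.7 macrophages that were left untreated or were treated for 8 h with LPS (100 ng/ml) and LPS-binding protein (100 pM) was compared on 6 two-colour arrays. Per the labels, untreated RNA was in Cy3 and treated RNA in Cy5 on 3 arrays, and the dyes were exchanged on the other 3. The labels name the line 264.7 in 42 places and 264.4 in 6, and the more frequent name is used here. Each of the 3 set numbers appeared once in each orientation. The labels do not say whether both arrays of a set carried the same RNA extracts, so each set was counted as 1 replicate. Same-numbered arrays of opposite orientation deviated from their orientation's mean together in the ratios as deposited (r of 0.284, 0.215 and 0.173 over genes), and each of the 6 arrays correlated best with its own number. The pairing was thus read from the data and the shared numbers. A deviation shared in that way has opposite signs once the ratios are turned, and cancels in the set mean. It therefore does not show that both arrays of a set carried the same RNA extracts. Averaged over the probes of each gene, no pair of arrays shared identical values other than 0.

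The values deposited by the authors were log2 ratios, 1 per feature and array. The log base was read from the values, since the largest was 6.643856, which is log2 of 100 and was reached on 3 arrays. The scanner software, background correction and dye normalization are not given in the sources used here. The median of each array was 0 as deposited, and 0.00095 to 0.0212 without values of exactly 0. The direction of the ratio was not stated. Arrays of opposite dye orientation correlated negatively as deposited (r of -0.768 to -0.404 over probes), so they had not been turned to one direction, and the ratio was read as Cy5 over Cy3 because the labels call Cy3 control and Cy5 test. No channel intensities were used here, so neither a filter on dim features nor a measure of signal over background could be applied, and only the number of arrays can be given as a limit on precision. Between 1328 and 2262 features per array, 8.16% to 13.9%, were listed at exactly 0. The 969 features at 0 on all 6 arrays were left out, and other zeros were kept as values in the reported fits.

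Features were named from the platform annotation. Of 16281 features, 13738 had 1 gene symbol, 52 had several and 2491 had none, and features with several symbols were not named. Of the 13738, 13694 matched a RefSeq gene of assembly GRCm38.p6 by gene identifier, 44 did not and kept the annotation's symbol, and 0 symbols changed. No coordinates are given because no build is tied to the array. All 6 value columns matched a sample by name.

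Ratios on the 3 arrays with treated RNA in Cy3 were multiplied by -1, so that every value was treated over untreated. The probes of a gene were averaged, which concerned 2459 genes with several probes. Both arrays of a set were then averaged, so that a dye effect cancelled in each set mean. The 3 set means of 10525 genes, and of 15312 probes, were tested against 0 with lmFit and eBayes in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene comes from limma. SDs are over the 3 set means unless stated otherwise.

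The tests, their alternatives, 29 gene lists and the rule for naming genes were fixed before the data were examined. The lists held 936 symbols, of which 769 were measured. They were tested with limma's camera (preset correlation 0.01, two-sided, adjusted over the 29 lists), with camera using an estimated correlation and fry beside it. Named genes were the 15 largest rises and 10 largest falls among genes with an adjusted p under 0.05 and the same sign on all 6 arrays. From each list came the 2 largest rises and 2 largest falls among members that passed, or the member with the smallest p where none did. Tlr4, Cd14, Ly96, Lbp, Nos2, Tnf, Il1b, Il6, Ptgs2 and Ccnd1 were always included. Clone, RIKEN, Gm, LOC and EST identifiers were passed over for the next gene. The rule gave 110 genes, of which the text gives a part.

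The procedure was tested on simulated set means for the treated over untreated comparison, drawn for the same 10525 genes with the spread limma estimated. With 50 genes changed at each size, 96% were called at a log2 change of 0.5 and 100% at 1, 2 and 4, with 16 false calls (7.48% of all calls). Of 2 lists shifted in a second simulated table, 2 were called, and 0 others were. Genes were drawn independently, whereas estimated correlations in the real lists ran from -0.104 to 0.366. The simulation therefore cannot show false list calls that come from correlation between genes. The share of genes changed was also far smaller than the 30.6% called in the data.

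Alternatives covered the 6 arrays as separate replicates with a dye term, without and with the set number as a block, median centring, scaling and quantile normalization between arrays, each dye orientation alone, and zeros treated as missing. They also covered robust moderation, a test against 1.5-fold (treat), a single probe per gene, other set tests, and each set left out in turn. For the lists, the fit with a block used cameraPR, which takes moderated t-statistics, in place of camera on the ratios. Zeros as missing with 2 of 3 sets enough, and zeros as missing with median centring, were added after the data had been seen, as were a test of the dye orientations on differences within sets and means of genes over values other than 0. Figures were drawn with matplotlib.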

Results

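RNA was measured in RAW 264.7 cells, a mouse macrophage line, that had been cultured for 8 h either untreated or with lipopolysaccharide (LPS) at 100 ng/ml and LPS-binding protein at 100 pM. LPS is the outer membrane component of Gram-negative bacteria that Toll-like receptor 4 recognises, and LPS-binding protein is the serum protein that passes LPS on to CD14. Treated and untreated RNA were hybridised together on 6 two-colour arrays. The arrays formed 3 numbered sets, each holding 1 array with treated RNA in Cy5 and 1 with treated RNA in Cy3. The table held 1 log2 ratio for each of 16281 features per array, and 969 features that were listed at exactly 0 on all 6 arrays were left out. Across genes, ratios turned to treated over untreated correlated between arrays of the same dye orientation with Pearson's r of 0.675 to 0.882, and between arrays of opposite orientation with r of 0.528 to 0.81. Genes are not independent replicates in these correlations. The number of arrays limits the precision of every value below.

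The comparison asked which transcripts differed between treated and untreated cells at 8 h. Of 45 measured interferon-stimulated genes 43 rose, and of 66 cell cycle and DNA replication genes 53 fell. The direction is a likely one, since the table does not state which dye was the numerator. It was read as Cy5 over Cy3 because the labels call the Cy3 channel control and the Cy5 channel test, and every sign below rests on that reading, so that rises and falls would exchange places under the opposite one. Of 10525 genes tested, 3218 (30.6%) had an adjusted p under 0.05 in limma's moderated test over the 3 set means, 1646 of them higher and 1572 lower in treated cells. Rises reached further than falls. Among these genes, 282 rose and 45 fell by more than 2-fold, while 45 rose and 0 fell by more than 8-fold. The median size of change of the 3218 genes was 0.36 on the log2 scale, and 2673 of them had the same sign on all 6 arrays. Among single probes, 4360 of 15312 passed, 2277 higher and 2083 lower, and these included 556 of the 2035 probes without a single gene symbol. Leaving out set 2 gave 1840 genes and leaving out set 3 gave 1596, against 2745 without set 1, and a test against a change of 1.5-fold gave 395. The labels do not say that the sets were separate cultures, so p-values measure the spread between these sets, which may be technical.

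Among the 15 named genes with the largest rises, Ifi204, an interferon-inducible member of the DNA-sensing family, had a log2 ratio of 4.72 ± 0.17 (SD, n = 3 sets), or 26.4-fold. Ifit2, an interferon-induced protein that binds viral RNA, rose by 4.65 ± 0.12 and Ifit3 by 4.31 ± 0.17. Rsad2, which encodes the antiviral enzyme viperin, rose by 4.53 ± 0.29, with means of 5.33 on the arrays with treated RNA in Cy5 and 3.73 on those with treated RNA in Cy3. Its genomic neighbour Cmpk2, a nucleotide kinase, rose by 4.43 ± 0.22. Ifnb1, the gene of interferon beta, rose by 4.30 ± 0.55, or 19.7-fold. The guanylate-binding protein genes Gbp3 and Gbp2 rose by 4.26 ± 0.34 and 3.84 ± 0.36, the interferon-inducible GTPase gene Tgtp1 by 3.98 ± 0.30, and the RNA sensor gene Ifih1 by 3.90 ± 0.16. Ifi202b averaged 4.15 ± 0.08 over 3 probes whose means ran from 0.06 to 6.24, and 5 of its values stood at the table's largest ratio of 100-fold. Its mean is therefore a lower bound, and its place among the 15 is not settled. Its SD and adjusted p may be too small for the same reason. The remaining 4 were Ccl2 (4.06 ± 0.22), which attracts monocytes, Cxcl10 (4.04 ± 0.22), which attracts activated T cells, the acute-phase gene Saa3 (3.95 ± 0.08) and the interleukin-1 receptor antagonist gene Il1rn (3.95 ± 0.17). Limma's adjusted p for these 15 genes was at most 0.000109, and each was higher on 6 of 6 arrays, as the naming rule required. Membership of the 15 also rests on keeping zeros and averaging probes. Acod1, with 2 values of exactly 0, averaged 5.49 on the other 4 arrays, and a probe of Isg15 averaged 4.25 beside one at -0.05.

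The 10 named genes with the largest falls were smaller in size. Cytip, a regulator of leukocyte adhesion, fell by 2.09 ± 0.24 on the log2 scale, or 4.26-fold. Id2, an inhibitor of helix-loop-helix transcription factors, fell by 1.76 ± 0.21. Tk1, the thymidine kinase of S phase, fell by 1.51 ± 0.08, and Esco2, which acetylates cohesin during DNA replication, fell by 1.45 ± 0.21. Cldn11, Sapcd2 and Myadml2 had log2 ratios of -1.55 ± 0.29, -1.55 ± 0.03 and -1.5 ± 0.28. Zfpm1, a cofactor of GATA factors, stood at -1.36 ± 0.14, Mmd at -1.35 ± 0.12 and Gask1b at -1.30 ± 0.33. Limma's adjusted p for these 10 genes was at most 0.00116, with 6 of 6 arrays lower for each, as the naming rule required.

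**Figure D1:**
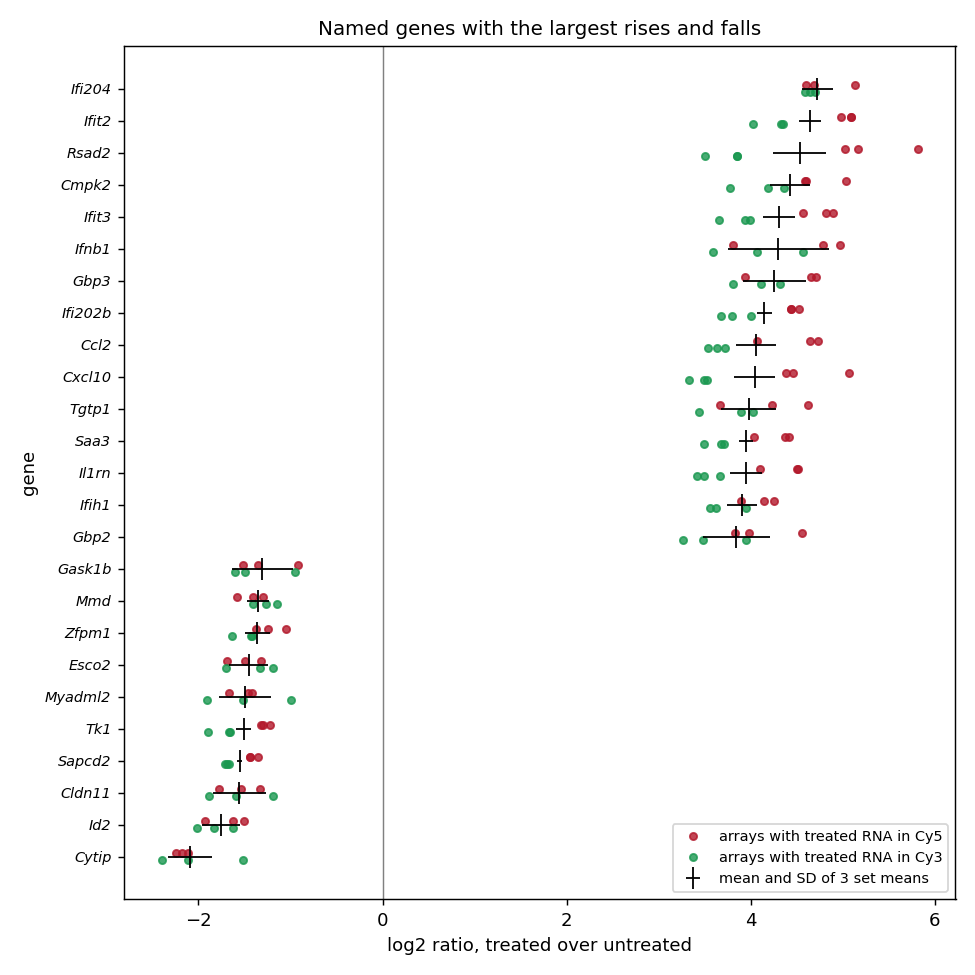
Log2 ratio of treated over untreated cells (horizontal axis) for the 15 named genes with the largest rises and the 10 with the largest falls (vertical axis). Points are single arrays, red with treated RNA in Cy5 and green with treated RNA in Cy3, and bars give the mean and SD of the 3 set means. Rises run from 3.84 for Gbp2 to 4.72 for Ifi204 and falls from -1.30 for Gask1b to -2.09 for Cytip.

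Of 45 measured interferon-stimulated genes, 43 rose and 0 fell, with a median log2 ratio of 2.57, and 44 rose when adjusted over the list alone. The list stood above the other genes in camera with a preset correlation of 0.01 (adjusted p = 1.37e-32), and the adjusted p was 0.203 with an estimated correlation. The 2 that did not pass, picked out after their values were seen, were Irgm1 (2.16 ± 1.88, limma's adjusted p = 0.0632) and Ifi30 (-0.13, adjusted p = 0.242). Each had 2 values of exactly 0. On the other 4 arrays Irgm1 had a mean of 3.23 ± 0.24 and Ifi30 one of -0.20 ± 2.21 (SD, n = 4 arrays). The values of Ifi30 ran from -2.15 to 1.91.

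Inflammatory cytokine genes rose in 19 of 27 cases and fell in 0, and the count was also 19 when adjusted over the list alone. Their median was 0.54 and camera's adjusted p was 4.85e-09, against an adjusted p of 0.203 with an estimated correlation. Il1b rose by 3.47 ± 0.57, Il6 by 3.26 ± 0.62 and Tnf by 1.89 ± 0.19 on the log2 scale (n = 3 sets). Of 23 chemokine genes, 12 rose and 1 fell, or 12 and 2 adjusted over the list alone, with a median of 0.59 and a camera adjusted p of 3.29e-05 (adjusted p = 0.203 with an estimated correlation). Cxcl14, a chemokine of epithelia, was the member that fell, at -0.75 ± 0.11.

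The NF-kappaB pathway list, which holds the transcription factor subunits and their feedback inhibitors, had 16 of 23 members that rose and 1 that fell, or 17 and 1 adjusted over the list alone. Its median was 0.48 (camera adjusted p = 6.5e-08, adjusted p = 0.203 with an estimated correlation). Nfkbiz, an atypical inhibitor protein, rose by 1.89 ± 0.19 (probe means 1.06 and 2.73) and Bcl3, a nuclear coactivator, by 1.71 ± 0.22. Of 32 immediate early and mRNA or MAP kinase feedback genes, 24 rose and 2 fell, or 25 and 3 adjusted over the list alone. The median of this list was 0.62 (camera adjusted p = 1.61e-10, adjusted p = 0.203 with an estimated correlation). Myc rose by 3.66 ± 0.46 and Zfp36, whose product destabilises cytokine mRNA, by 2.05 ± 0.10, while the transcription factor gene Klf2 stood at -1.0 ± 0.06.

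Among 24 genes of LPS recognition and Toll-like receptor signalling, 11 rose and 3 fell, with the same counts adjusted over the list alone. The median was 0.18 (camera adjusted p = 0.00262, adjusted p = 0.203 with an estimated correlation). Tlr3, the receptor for double-stranded RNA, rose by 3.18 ± 0.38 and Peli1, a ubiquitin ligase of the pathway, by 1.01 ± 0.13. Tab1, an adaptor of the kinase TAK1, stood at -0.62 ± 0.04. The LPS receptor's own genes differed. Ly96, which encodes the coreceptor MD-2, rose by 0.86 ± 0.01 (limma's adjusted p = 0.00013), whereas Tlr4 stood at -0.50 ± 0.15 (adjusted p = 0.00392). The 3 Tlr4 probes had means from -0.83 to -0.05, and with the probe of smallest spread standing for the gene its log2 ratio was -0.05 (adjusted p = 0.416). Cd14 had a log2 ratio of 0.02 ± 0.11 (adjusted p = 0.868) and Lbp one of 0.04 ± 0.32 (adjusted p = 0.823).

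In the list of nitric oxide, arginine and itaconate metabolism, 6 of 12 genes rose and 2 fell, or 7 and 2 adjusted over the list alone. Its median was 0.53 (camera adjusted p = 0.00741, adjusted p = 0.203 with an estimated correlation), and camera gave an adjusted p of 0.16 on the arrays with treated RNA in Cy5 alone. Nos2, the inducible nitric oxide synthase, rose by 1.17 ± 0.16 and Gch1, which starts synthesis of its cofactor tetrahydrobiopterin, by 2.39 ± 0.10. Acod1, which makes itaconate, averaged 3.66 ± 1.90 with 2 of its 6 values at exactly 0 (limma's adjusted p = 0.0115), and 5.49 ± 1.01 over the other 4 arrays (SD, n = 4 arrays). With zeros as missing it had too few values for the test, and with zeros kept its adjusted p was 0.116 and 0.152 in the arrays of each dye orientation alone.

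Antigen presentation and costimulation genes rose in 16 of 25 cases and fell in 0, and 16 rose adjusted over the list alone. The median was 0.57 (camera adjusted p = 4.85e-09, adjusted p = 0.203 with an estimated correlation). Cd40, a costimulatory receptor, rose by 3.76 ± 0.18, and Tap1, a subunit of the peptide transporter for MHC class I, by 2.37 ± 0.13. Of 20 complement and acute-phase genes, 9 rose and 0 fell, also when adjusted over the list alone. Camera's adjusted p for this list was 0.000334 at a median of 0.18, and the adjusted p was 0.444 with an estimated correlation. Saa3 led it, followed by C3ar1, the receptor for C3a, at 2.73 ± 0.14. Apoptosis regulators rose in 14 of 28 cases and fell in 4, or 14 and 5 adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.000326, adjusted p = 0.203 with an estimated correlation). The death receptor gene Fas rose by 2.72 ± 0.09 and Bcl2a1a, a survival gene, by 2.23 ± 0.12, while Pmaip1, which encodes the pro-death protein Noxa, stood at -0.62 ± 0.08.

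Cell cycle and DNA replication genes were lower in treated cells. Of 66 measured, 53 fell and 1 rose, or 55 and 2 adjusted over the list alone, and the median was -0.56. Camera's adjusted p was 1.19e-18, and the adjusted p was 0.203 with an estimated correlation. Besides Tk1, the cyclin A gene Ccna2 stood at -1.21 ± 0.16. The member that rose was the D-type cyclin gene Ccnd2 (0.48 ± 0.06). Ccnd1 had a log2 ratio of 0.13 ± 0.05 over 2 probes with means of 0.01 and 0.25 (limma's adjusted p = 0.091). Its adjusted p was 0.0329 with the set number as a block and 0.0297 with the 6 arrays as separate replicates. Treating values of exactly 0 as missing left out the whole probe at 0.01, which held 1 of them, and gave 0.25 (adjusted p = 0.00593). With only that 0 left out, the mean of Ccnd1 was 0.15 ± 0.09 (SD, n = 6 arrays). In the list of cyclin-dependent kinase inhibitors and p53 targets, 6 of 17 genes rose and 5 fell, or 6 and 7 adjusted over the list alone (camera adjusted p = 0.765). Cdkn1a, which encodes the inhibitor p21, rose by 1.02 ± 0.06 (probe means from 0.40 to 1.35) and Plk2 by 1.10 ± 0.12 (0.47 and 1.72), whereas Cdkn2c stood at -0.82 ± 0.05 and Rbl2 at -0.68 ± 0.08.

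**Figure D2:**
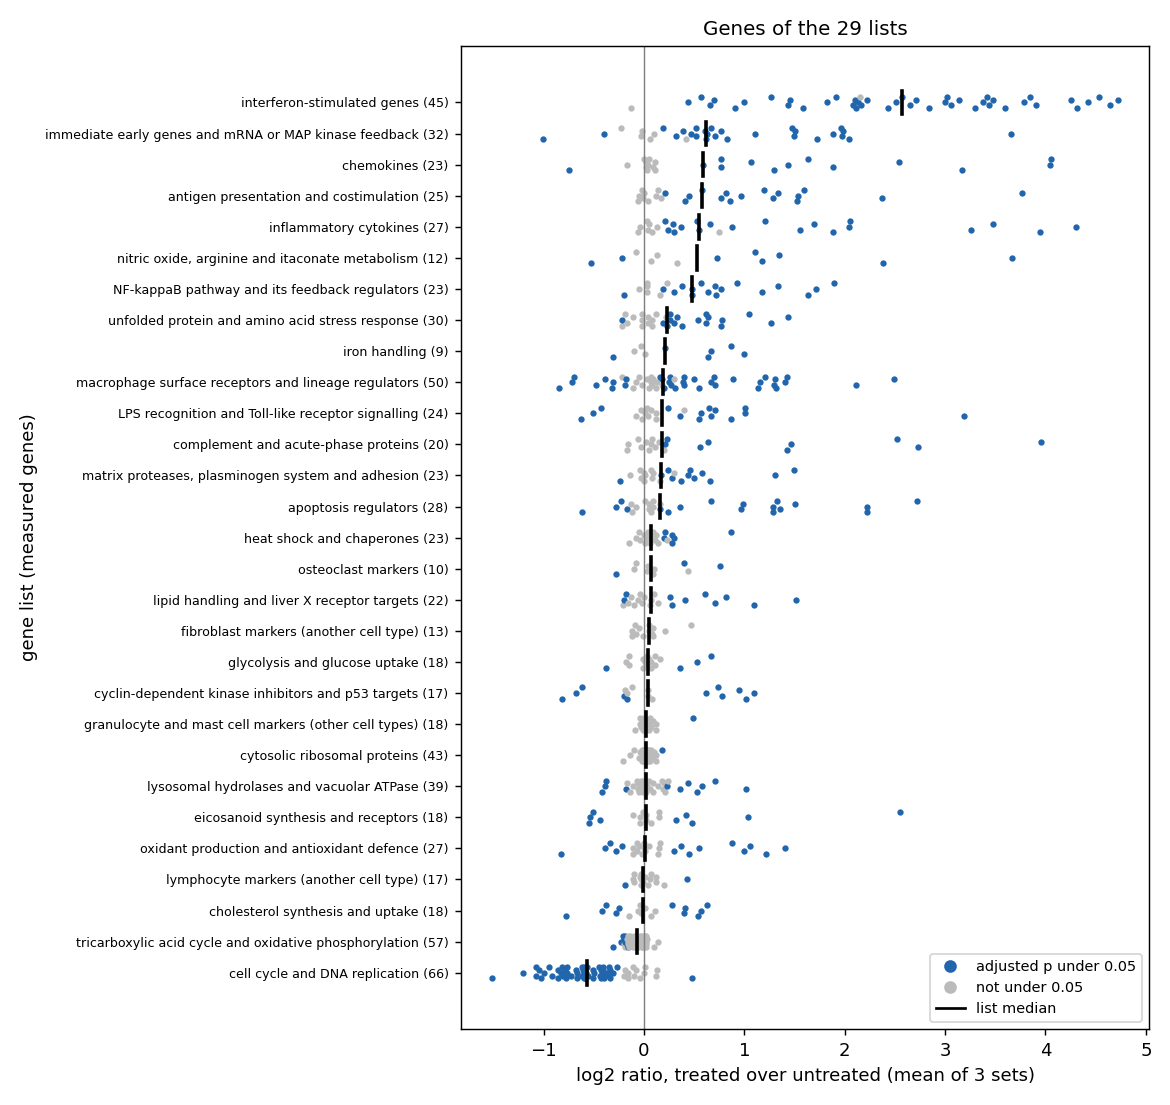
Log2 ratio of treated over untreated cells (horizontal axis, mean of 3 sets) for each measured gene of the 29 lists (vertical axis, number of measured genes in brackets). Blue points have an adjusted p under 0.05, grey points do not, and black bars are list medians, which run from -0.56 for cell cycle and DNA replication to 2.57 for interferon-stimulated genes.

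Surface receptor and lineage genes of macrophages moved in both directions. Of 50 measured, 26 rose and 9 fell, or 28 and 10 adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.000105, adjusted p = 0.203 with an estimated correlation). The receptor tyrosine kinase gene Axl rose by 2.49 ± 0.50 and Fcgr1, the high-affinity IgG receptor, by 2.11 ± 0.10, while the lipid-sensing receptor gene Trem2 stood at -0.85 ± 0.07. Of 23 genes for matrix proteases, the plasminogen system and adhesion, 11 rose and 1 fell, with the same counts adjusted over the list alone. This list had a median of 0.17 (camera adjusted p = 0.000781, adjusted p = 0.203 with an estimated correlation). Plaur, the urokinase receptor, rose by 1.5 ± 0.03 and the proteoglycan gene Sdc4 by 1.30 ± 0.05.

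The unfolded protein and amino acid stress list had 16 of 30 members that rose and 1 that fell, or 17 and 3 adjusted over the list alone, at a median of 0.23 (camera adjusted p = 0.000113, adjusted p = 0.203 with an estimated correlation). Ddit3, the stress-induced transcription factor CHOP, rose by 1.44 ± 0.12 and Dnajb9, a chaperone of the endoplasmic reticulum, by 1.26 ± 0.13. Heat shock and chaperone genes rose in 6 of 23 cases and fell in 0, also when adjusted over the list alone, and Dnajb4 rose by 0.87 ± 0.05. Camera's adjusted p for this list was 0.0135, and the adjusted p was 0.203 with an estimated correlation, 0.182 with the set number as a block and 0.37 on the arrays with treated RNA in Cy5 alone.

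Genes of the tricarboxylic acid cycle and oxidative phosphorylation shifted little. Of 57 measured, 8 fell and 0 rose, or 1 and 0 adjusted over the list alone, at a median of -0.07. Camera's adjusted p was 0.0053, and the adjusted p was 0.313 with an estimated correlation, 0.0921 with the set number as a block and 0.1 on the arrays with treated RNA in Cy3 alone. Fh1, the fumarate hydratase gene, stood at -0.31 ± 0.02 (limma's adjusted p = 0.00435), and its adjusted p was 0.0503 without set 3. Glycolysis and glucose uptake genes rose in 3 of 18 cases and fell in 1, also when adjusted over the list alone (camera adjusted p = 0.4), and Hk2, a hexokinase gene, rose by 0.67 ± 0.11. In both lists, zeros kept as values pull means toward 0. Atp5o, Cox5a and Pgk1, picked for their zeros, had 5, 4 and 4 of them. Without these zeros their means were -0.11, -0.06 and 0.21.

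Lipid handling genes and liver X receptor targets rose in 8 of 22 cases and fell in 2, also when adjusted over the list alone. The list's median was 0.07 and camera's adjusted p 0.0492, and the adjusted p was 0.374 with an estimated correlation, 0.123 without set 1 and 0.094 without set 2. It was also 0.0551 with the 6 arrays as separate replicates, 0.0672 after scaling, 0.06 after quantile normalization, and 0.181 and 0.0546 with treated RNA in Cy5 alone and in Cy3 alone. Fabp4, a fatty acid carrier, averaged 1.52 ± 0.12 over 2 probes with means of 0.38 and 2.65, and Npc2, a lysosomal sterol carrier, rose by 1.10 ± 0.02. Of 18 genes of cholesterol synthesis and uptake, 6 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.764). The median of that list was -0.01, while its mean was 0.04 and camera's direction was up. Hsd17b7 rose by 0.62 ± 0.03, and the desaturase gene Scd1 stood at -0.77 ± 0.05.

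In the list of oxidant production and antioxidant defence, 9 of 27 genes rose and 5 fell, or 11 and 5 adjusted over the list alone (camera adjusted p = 0.278). Cybb, the catalytic subunit of the phagocyte oxidase, rose by 1.41 ± 0.14, and Gclc, which starts glutathione synthesis, stood at -0.82 ± 0.07. Eicosanoid genes rose in 5 of 18 cases and fell in 4, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.655). Ptgs2, the inducible cyclooxygenase, rose by 2.56 ± 0.66 and Hpgds, a prostaglandin D synthase, stood at -0.53 ± 0.12. Of 39 lysosomal genes, 7 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.278), and the protease gene Ctsc rose by 1.02 ± 0.07. Iron handling genes rose in 5 of 9 cases and fell in 1, also when adjusted over the list alone. Camera's adjusted p for them was 0.068, and 0.0425 without set 3, and the haem oxygenase gene Hmox1 rose by 1.00 ± 0.17. Of 10 osteoclast markers, 2 rose and 1 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.326), and the proton pump gene Tcirg1 rose by 0.76 ± 0.13.

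Markers of other cell types and ribosomal protein genes moved little with zeros kept as values, which pull means toward 0. Rps21 and Rpl10, picked for their zeros, each had 1 array not at 0, with values of 0.43 and 0.01. Of 13 fibroblast markers 0 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.765). Pdgfra, which had the smallest p of that list, stood at 0.21 ± 0.14 and was above 0 on 4 of 6 arrays (limma's adjusted p = 0.0631). Its adjusted p was 0.0447 with zeros as missing, although it had no 0 itself, and 0.035 after quantile normalization, against 0.549 with the set number as a block. Of 17 lymphocyte markers, 1 rose and 1 fell, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.765), with a median of -0.01 and a mean of 0.03. The immunoglobulin gene Ighm averaged 0.42 ± 0.08 over 5 probes with means from -0.09 to 0.67. The other was Cd8b1 at -0.18 ± 0.07, with 2 probes at -0.42 and 0.05, whose adjusted p was 0.121, 0.0744 and 0.215 without sets 1, 2 and 3. Of 18 granulocyte and mast cell markers, 1 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.425). It was Elane at 0.49 ± 0.22 over 2 probes with means of 0.10 and 0.88, with an adjusted p of 0.0787 without set 3 and 0.178 with the probe of smallest spread standing for the gene. Of 43 ribosomal protein genes, 1 rose and 0 fell, or 0 and 0 adjusted over the list alone, at a median of 0.02 (camera adjusted p = 0.463). It was Rps28 at 0.18 ± 0.06, with adjusted p of 0.118, 0.105 and 0.182 without sets 1, 2 and 3, 0.0647 after scaling, 0.0541 after quantile normalization and 0.85 with treated RNA in Cy5 alone.

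Across the 29 lists, 17 passed in camera with the preset correlation and 0 with an estimated correlation, while 21 passed in fry, which tests whether the genes of a list move, on balance, one way. In camera with an estimated correlation, the lists that shared an adjusted p of 0.203 differed before adjustment. Their unadjusted p ran from 0.00967 for interferon-stimulated genes to 0.0979 for heat shock and chaperones. The rise in p from the preset setting is not a measure of correlation between genes alone. It also occurred where the estimate was below the preset 0.01, as for the NF-kappaB list (-0.043).

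Changes over 8-fold were larger on the arrays with treated RNA in Cy5. The 45 genes that rose by more than 8-fold had a median log2 ratio of 3.90 ± 0.11 (SD, n = 3 arrays) with treated RNA in Cy5 and 3.40 ± 0.08 with treated RNA in Cy3. The 56 genes that rose 4-fold to 8-fold had medians of 2.39 ± 0.08 and 2.25 ± 0.06, higher with treated RNA in Cy5 in all 3 sets. The 181 genes that rose 2-fold to 4-fold had medians of 1.35 ± 0.02 and 1.33 ± 0.03, and the 1364 that rose by less than 2-fold had medians of 0.33 ± 0.01 and 0.38 ± 0.03, lower with treated RNA in Cy5 in all 3 sets.

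**Figure D3:**
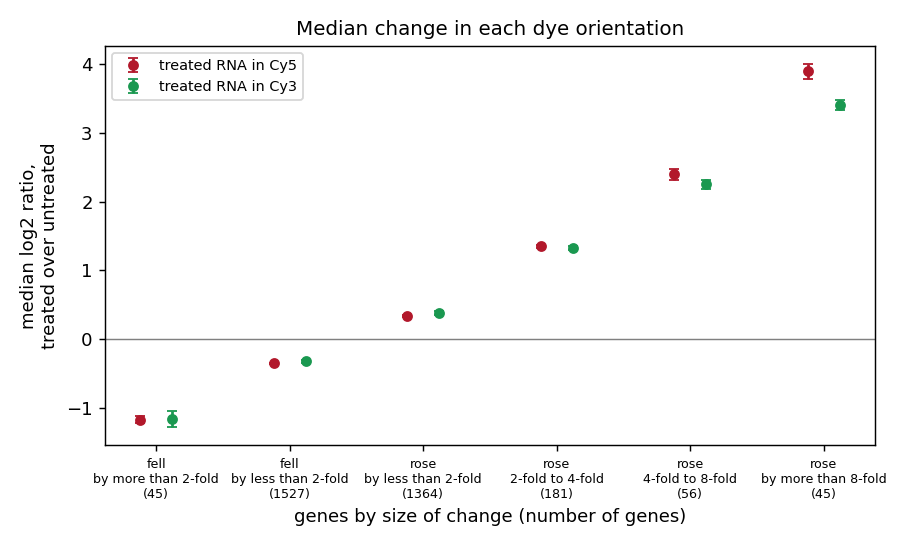
Median log2 ratio of treated over untreated cells (vertical axis) for genes past the threshold, grouped by the size of their change (horizontal axis, number of genes in brackets). Points are the mean over 3 arrays of each array's median and bars the SD, red with treated RNA in Cy5 and green with treated RNA in Cy3. The orientations stand apart most for rises over 8-fold, at 3.90 against 3.40.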

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

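Of the tests in this part, 4 were chosen only after a result was seen. They are the paired test of the dye orientations, the comparison of 2-fold to 4-fold rises between the dye orientations, the count of single zeros beside large changes, and the precision of probes without a 0.

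A dye term in the 6-array limma fit tested whether the change differed between the orientations. It passed for 115 of 10525 genes, with 2654 at an unadjusted p under 0.05. That fit treats the arrays as separate, although same-numbered arrays deviated together. With the differences taken within the 3 sets, limma called 0 genes (smallest adjusted p = 0.124, with 2494 at an unadjusted p under 0.05). The differences are the same in both tests, and the paired one has 3 values per gene. Its 0 calls therefore do not show that differences between the orientations were absent. In the 6-array fit, the treated over untreated ratio was higher with treated RNA in Cy5 for 69 genes and lower for 46. Of the 115, 32 also passed the treatment test, against 30.6% of all genes in the test over the 3 set means. The named genes among the 115 were interferon-induced. Rsad2 averaged 5.33 with treated RNA in Cy5 and 3.73 with treated RNA in Cy3, a difference of 1.60 ± 0.34 on the log2 scale (SD over 3 sets, unadjusted p = 0.000867 in the paired limma test). The differences were 0.90 ± 0.02 for Ifit3 (unadjusted p = 0.00016), 0.82 ± 0.12 for Ifit2 (unadjusted p = 0.000639) and 0.64 ± 0.18 for Ifi202b (unadjusted p = 0.0035), and the adjusted p of each of the 4 was 0.141. Ifi202b had values at the table's largest ratio.

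Rises over 8-fold were larger with treated RNA in Cy5 by 0.59 ± 0.13 on the log2 scale (median over 45 genes, SD over 3 sets), while those under 2-fold were smaller by 12.6% ± 9.21, in all 3 sets (1364 genes). A wider ratio scale on those arrays would make falls larger too, and in the test set for it beforehand the median difference of fallen genes was below 0 in all 3 sets, the outcome that explanation needs, but its mean of -0.02 ± 0.02 (-0.0218) was no larger than its spread. In a second test, chosen after that outcome, rises of 2-fold to 4-fold were larger with treated RNA in Cy5 by 1.75% ± 3.66, against 14.4% ± 1.47 for rises over 8-fold, so one wider scale at every ratio would not account for the difference by itself. Rises of 4-fold to 8-fold, which that test did not use, lay between, larger by 6.23% ± 2.90. A lower floor of the Cy3 channel for the dimmer RNA would make falls larger with treated RNA in Cy3. The rule set beforehand counted a median difference at or below 0 in all 3 sets against this floor, and that was the outcome. The same mean of -0.0218, no larger than its spread, still leaves the floor open, because few falls were large and no intensities were used here. No biological explanation was tested.

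Exact zeros stood beside large changes. Of 1079 features with a single 0, 16 had the other 5 ratios on one side with a median size over 1 on the log2 scale. A probe of Il1b averaged 3.27 ± 0.22 (SD, n = 5 arrays) and 1 of Ccrl2 averaged 2.56 ± 0.18 on the arrays where they were not 0. The table held 11208 exact zeros and 17 other values within 0.0001 of 0. The excess of exact zeros is what a placeholder for features not measured on an array would give. The 16 features were counted after such zeros had been seen, so they illustrate the pattern and add no separate support. No biological explanation was tested.

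Probes of one gene disagreed in some of the strongest responses. Of 146 genes with several probes and a passing probe over 2-fold, 41 also had a probe with a mean under 0.3 in size, 49 such probes in all. Rb1cc1, picked after its values were seen, had probe means of 4.34 and 0.27 with no value at exactly 0, while the probe of Isg15 at -0.05, beside one at 4.25, was at exactly 0 on 5 arrays. Lower precision of the silent probes was tested by 2 ratios fixed beforehand, either of which could show it at over 1.5. The SD between sets was 1.39 times that of all probes, and zeros were 1.97 times as frequent, so the second met the bound, but a 0 pulls a mean toward 0 and favours that outcome by construction. Over the 34 silent probes without a 0 the SD ratio was 1.32, between the bounds of 1.2 and 1.5, which leaves lower precision open, and probes that match another transcript or splice form were not tested.

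The 6 arrays can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. In the 6-array fit the real split gave 3631 genes, 5073 probes and 16 lists, the largest count in 1 of 10 splits each time, and the highest other split gave 0 genes, 5 probes and 13 lists. Each other split mixes the orientations, so part of the treatment effect stays in its ratio and the rest adds to its spread. Few gene calls there were thus built in, and these splits do not measure false calls. The 4 to 13 lists they called may hold treatment effect or false calls, which were not told apart.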

How the results depend on the processing

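Of the alternatives, those with zeros as missing and either 2 of 3 sets enough or median centring were chosen after the data had been seen, as were the pairing by set of the test between dye orientations and means over values other than 0. Among named genes, means over values other than 0 changed Acod1 most (log2 ratio of 5.49 against 3.66), by the factor that leaving out 2 of 6 values fixes. Counts of genes, probes and lists stayed within 1.5 times the reported ones under each alternative except those given here. Treat at 1.5-fold gave 395 genes (321 higher, 74 lower) and 600 probes (485 higher, 115 lower), as its stricter null requires. The arrays with treated RNA in Cy3 alone gave 2132 genes, 990 of them lower, and 1334 lower probes, and the cause was not tested. Leaving out 1 set gave 1596 to 2745 genes (905 to 1438 higher, 691 to 1307 lower) and 1983 to 2880 probes (1134 to 1613 higher, 831 to 1267 lower), with fewer replicates in each fit, and 16 to 18 lists. Gene counts were lowest without set 3 (1596) and set 2 (1840). Camera with an estimated correlation called 0 lists against 17, and the cause was not tested. A correlation above the preset 0.01 cannot be the cause for every list. The estimate was below it for the NF-kappaB (-0.043), antigen presentation (-0.0023) and chemokine (-0.023) lists. Their unadjusted camera p still rose, from 1.34e-08, 6.80e-10 and 7.93e-06 to 0.0244, 0.0205 and 0.0387. Other lists had a higher estimate, such as complement and acute-phase genes (0.366). With zeros as missing, 3482 of 9192 genes passed. With the set number as a replicate block, 3540 genes, 4945 probes and 15 lists passed, against 3631, 5073 and 16 for the 6 arrays without it. Between those fits the heat shock list (adjusted p = 0.182) and the tricarboxylic acid cycle and oxidative phosphorylation list (0.0921) lost their calls. The lipid handling list had an adjusted p of 0.0255 against 0.0551, and no other call among the named genes and lists changed. The list test changed together with the block, from camera to cameraPR, and the correlation within sets was 0.061 over genes. These list changes therefore cannot be credited to the block alone. The test between dye orientations called 0 genes when paired by set against 115 unpaired. Of 106 named genes past the threshold, 22 lost their call without some set (6 without set 1, 16 without set 2, 19 without set 3), 42 under treat, 17 with treated RNA in Cy3 alone and 10 with treated RNA in Cy5 alone, and 0 of the 110 named genes and 29 lists reversed with a call. Scaling or centring moved the share of higher calls between 50.7% and 51.4%. Not run were the filter on dim or flagged probes, because the table held no signal or flag, the rule on missing values by itself, because none were missing, and another log base, which the largest value settled. Signal over background is unknown.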

Other observations

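Gene families grouped by the stem of their symbol, 177 with at least 8 measured genes, were tested with camera after the data had been seen, and 9 had an adjusted p under 0.05. With an estimated correlation the adjusted p was 0.993 for each family given here. Of 12 Psmd genes, which encode the regulatory particle of the proteasome, 7 rose and 0 fell (camera adjusted p = 0.0246), Psmd8 with a log2 ratio of 0.45 ± 0.07 (SD, n = 3 sets). Of 10 Psmb genes, which encode its catalytic core, 4 rose and 0 fell (adjusted p = 0.0426), led by the immunoproteasome subunits Psmb10 (1.53 ± 0.04) and Psmb8 (1.34 ± 0.09), and 3 of the 10 were in the fixed lists. Of 8 Psma genes, 4 rose and 0 fell (adjusted p = 0.054). Syntaxin genes, whose products take part in membrane fusion, rose in 7 of 13 cases and fell in 0 (adjusted p = 0.0426), with Stx11 at 0.89 ± 0.28 and Stx6 at 0.48 ± 0.03. Genes in these families were picked for mention after their values were seen.

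Nucleoporin genes, which encode the nuclear pore, fell in 6 of 9 cases and rose in 0 (adjusted p = 0.0246), with Nup107 at -0.47 ± 0.13 and Nup155 at -0.41 ± 0.06. Of 12 genes with the stem Rad, most of them for DNA repair, 6 fell and 0 rose (adjusted p = 0.0494), with Rad54l at -0.82 ± 0.07. Annexin genes rose in 7 of 12 cases and fell in 0, but the family missed the threshold (adjusted p = 0.054), and Anxa3 stood at 1.18 ± 0.13.

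Gapdh, often used as a reference gene, was represented by 25 spots, of which 14 to 17 per array were not at 0. Their median treated over untreated ratio lay between -0.06 and 0.16 on the log2 scale, while single spots ran from -2.60 to 2.69. The spread followed the dyes. The lowest spot was at -2.45, -2.60 and -0.61 on the arrays with treated RNA in Cy5, and the highest at 2.69, 1.48 and 1.24 on those with treated RNA in Cy3.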
